A study of Mus musculus with 6 samples.

How the data were processed

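Gene expression was measured in the first lumbar segment of the spinal cord (L1) of male mice with severe combined immunodeficiency (SCID). Per the labels, mice were 9 weeks old at the start and 15 weeks old at sampling, 6 weeks after injection. There were 3 groups of 2 arrays. In the N-inv group, Capan-1 cells, a human pancreatic cancer line, were injected into the left sciatic nerve. In the SC group the same cells were placed under the skin. The PBS group was the vehicle control. Nothing in the labels says in words that the 2 arrays of a group came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may in part be technical.

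Per the labels' protocols, RNA was extracted with TRIzol, and biotin-labelled cRNA was made from 100 ng of total RNA by two-cycle labelling for Affymetrix 3' expression arrays. The deposited values are linear probe set intensities, 1 column per array. The 2% trimmed mean of each deposited array was 1000, which shows that the intensities had been scaled per array before deposit. The method that summarised probes into probe sets is not given in the sources used here. The lowest deposited intensity was 0.3 and the array medians lay between 241.7 and 279.2.

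The table held 45101 probe sets, and 64 control probe sets were left out. Of the remaining 45037, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160. Probe sets with several symbols were tested but not named. The RefSeq gene table of assembly GRCm38.p6 was used for names alone, to find list genes under their synonyms, and no coordinates are given because the files name no build. Each array was scaled to the common median of 256.2, and log2(intensity + 25.6) was taken, the pseudocount being the median divided by 10. A fold change on this scale understates the change of dim genes. Probe sets whose mean over the 6 arrays lay above the 40th percentile were kept, which left 27022 probe sets for 12614 named genes. The cutoff corresponds to an intensity of 147.7. A gene is represented by its brightest probe set.

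Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, in 1 model over all 6 arrays with a mean per group. The model had 3 residual degrees of freedom and a prior of 3.72. Benjamini-Hochberg adjustment ran over all probe sets tested, with a threshold of 0.05. There were 4 comparisons: N-inv against PBS, N-inv against SC, SC against PBS, and N-inv against the mean of both controls. No depth is defined for arrays, and their number limits the precision. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333. For 2 against 4 the bound is 0.133 when the one-sided p is doubled. No such test was therefore used.

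Gene lists for pathways and cell types were fixed before the data were examined, 44 in all, and 39 had the minimum of 5 measured genes. They were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 39 lists. Camera compares the genes inside a list with those outside it. At the preset correlation its p rests on that assumed value, so it is not a measure of the spread between arrays alone. Camera with an estimated correlation and fry were run beside it on all 39 lists. Fry tests whether the genes of a list move in a common direction on balance and does not compare them with other genes. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 0, 1, 0 and 1 lists in the order of comparisons given above. Its test for change in either direction called 1, 2, 4 and 1 lists in that order, with smallest adjusted p of 0.000965, 0.0102, 0.0255 and 0.00491. The skeletal muscle, adipocyte, blood and lymphocyte lists had 4, 2, 4 and 2 measured genes and were not tested. Some lists share genes: the axon injury and pain neuropeptide lists share 4, and the microglia and complement lists share 3.

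Genes were named by a rule fixed before the data were examined. Where genes passed the threshold, the 12 with the largest change in each direction were to be named. Otherwise up to 8 genes per direction were taken by the widest gap between the arrays of the groups. For each list described, 2 to 4 members with the smallest p were taken, and Gfap, Aif1, Fos, Atf3 and the sex-linked genes were always reported. A gene named outside the rule is said to be chosen after its values were seen.

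The scripts were tested on simulated data. For N-inv against PBS over 27022 probe sets, 28 of 67 probe sets changed by 1 on the log2 scale were called, 67 of 67 changed by 2 and 66 of 66 changed by 3, with 13 unchanged probe sets called. The simulation draws the spread from the fitted model, whose variances are drawn toward a common value and so differ less between probe sets. In both simulated comparisons the share called can therefore be higher than in the data. In N-inv against PBS, for example, Sprr1a had a log2 difference of 4.63 and was not called, so an absence of calls does not exclude large changes. For N-inv against both controls, the counts were 43 of 67, 67 of 67 and 66 of 66, with 15 unchanged probe sets called. On null data, with the noise of each gene drawn independently, 0.03% of lists were called. Genes of a list were uncorrelated in all these simulations, so the rate does not apply to lists whose genes are correlated. A list shifted by 0.5 reached an adjusted p of 3.06e-21 with the preset correlation and 0.0632 with an estimated one in the simulated comparison of N-inv with PBS, and 8.01e-26 and 0.0473 in that of N-inv with both controls.

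The alternatives were no filter, a filter at the 60th percentile, quantile normalization, values as deposited, pseudocounts of 1 and of the median, an intensity trend, robust variances, array weights, only the groups compared, the replicate number as a block, the mean over a gene's probe sets, an estimated correlation, another threshold, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.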

Results

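The title of the study names invasion of nerves by pancreatic cancer, activation of astrocytes and cachexia. Expression in the L1 cord was compared between mice with Capan-1 cells in the sciatic nerve (N-inv), mice with the same cells under the skin (SC) and vehicle controls (PBS), with 2 arrays per group. All values are scaled intensities.

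The 2 arrays of the SC group stood apart from the others and from each other. Their correlation with each other was 0.965, the lowest of any pair of arrays. Their median correlations with the other arrays were 0.972 and 0.971, against 0.981 in each of the other 4 arrays. The 3' to 5' ratio of the Actb control probes, a sign of RNA quality, was 3.81 and 4.71 in the SC arrays and between 3.05 and 3.57 in the others. The same ratio of the Gapdh control probes was 3.52 and 3.38 in SC, 3.13 and 3.38 in N-inv and 2.82 and 3.02 in PBS. The sex-linked genes were read as a check of the labels, which give all mice as male. The Y-linked genes Eif2s3y, Kdm5d and Uty were measured in all 6 arrays, with Eif2s3y at 1344 in SC replicate 1 and between 2369 and 3152 in the other 5. Xist, the RNA that silences an X chromosome in female cells, was at 13060 in SC replicate 2 and between 138.6 and 228.5 in the other 5 arrays. SC replicate 2 was kept in the comparisons, and values without it are given where it decides a call.

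**Figure D1:**
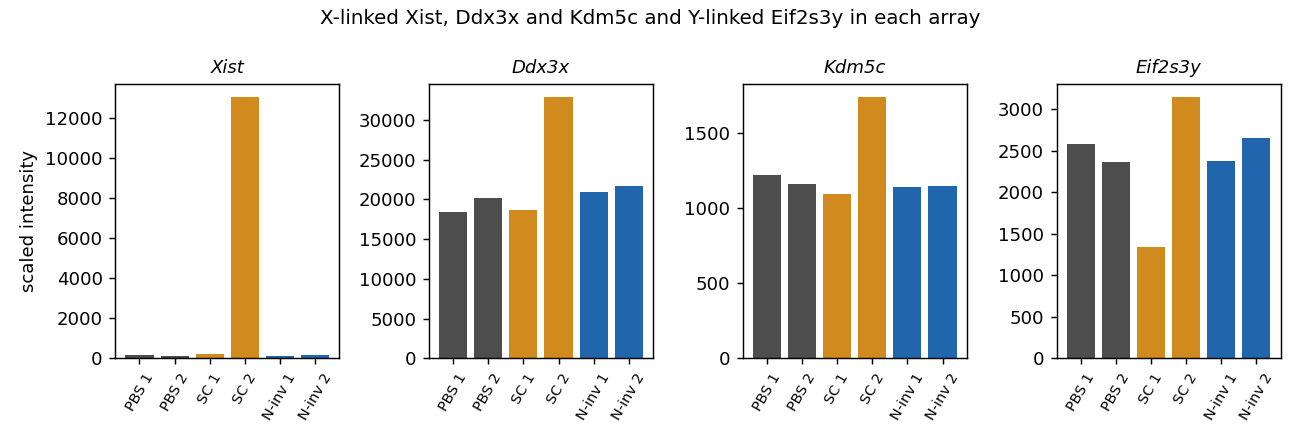
Scaled intensity of the X-linked genes Xist, Ddx3x and Kdm5c and the Y-linked gene Eif2s3y in each of the 6 arrays, with 1 bar per array. Xist stands at 13060 in SC replicate 2 and at 228.5 at most in the others.

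The first comparison set the nerve tumour model against the vehicle control. Genes of the microglia list rose as a group in N-inv, with a median log2 difference of 0.50 over 25 genes, of which 24 were higher (adjusted p = 3.02e-17 in camera, and adjusted p = 0.0859 with an estimated correlation). The 7 genes of macrophages of the meninges and vessel walls above the filter had a median of -0.05. Genes of the response to axon injury, of reactive astrocytes and of MHC class I antigen presentation also rose, by medians of 0.37, 0.32 and 0.36. Their adjusted p was 3.9e-08, 1.27e-06 and 1.7e-05, and adjusted p = 0.597 for each with an estimated correlation. In fry the microglia list had an adjusted p of 0.0764 and 0 lists were called, and for change in either direction its adjusted p was 0.000965. The Gapdh 3' to 5' ratios were also higher in N-inv, 3.13 and 3.38 against 2.82 and 3.02 in PBS. Gfap, the intermediate filament of astrocytes, measured 19860 ± 925 in N-inv and 7296 ± 893 in PBS (SD, n = 2 each), a log2 difference of 1.45 ± 0.50 (SE). No single gene passed the adjusted threshold, so gene values are given without a claim of change.

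Among microglia genes, Mpeg1, a pore-forming protein of phagocytes, measured 1874 and 1582 in N-inv against 913.6 and 1001 in PBS. The complement component C1qc measured 1607 and 1603 against 960.0 and 859.7, and the signalling adaptor Tyrobp measured 1137 and 1287 against 724.9 and 679.1. Aif1, which encodes the microglial marker IBA1, measured 416.5 ± 73.5 against 204.3 ± 55.0 (SD, n = 2 each). In the microglia list 9 of the 25 genes were called higher when adjusted over the list alone, and 0 over all genes tested.

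Of 26 axon injury genes 22 were higher in N-inv, and 8 were called when adjusted over the list alone. Sprr1a, a protein of regenerating neurons, measured 4143 and 3367 in N-inv and 112.6 and 141.6 in PBS, a log2 difference of 4.63 ± 0.96 (SE). The transcription factor Atf3, induced in neurons with damaged axons, measured 694.9 ± 132 against 187.4 ± 73.5 (SD, n = 2 each). The cell surface proteoglycan Sdc1 measured 282.2 and 305.0 against 183.1 and 104.0. The neuropeptide Gal measured 1806 and 1260 against 584.1 and 533.8, and the peptidase Ecel1 measured 2287 and 2125 against 1121 and 1398.

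In the reactive astrocyte list 24 of 30 genes were higher and 0 were called over the list alone. Its members with the smallest p were Aspg, at 779.2 and 656.7 against 249.3 and 297.8, the protease inhibitor Serpina3n, at 3829 and 3375 against 1288 and 1396, and Lcn2, an iron-siderophore binding protein, at 797.3 and 854.6 against 217.7 and 135.3. All 12 MHC class I genes were higher, among them H2-D1 at 8897 and 7389 against 5175 and 4994 and H2-K1 at 5269 and 4288 against 3345 and 3132, and 0 were called over the list alone. Without N-inv replicate 1 the MHC class I list had a median of 0.18 and was no longer called, and without N-inv replicate 2 it was at 0.62. The list of homeostatic astrocyte genes had a median of 0.10 and an adjusted p of 0.0879, and was called with an intensity trend, at 0.10 with an adjusted p of 0.0157.

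Pain neuropeptide genes rose by a median of 0.12 over 28 genes, 19 of them higher and 9 lower, with Tac1, the precursor of substance P, at 9169 and 9327 in N-inv against 3385 and 4779 in PBS and Pnoc, the precursor of nociceptin, at 621.2 and 823.6 against 380.6 and 436.9. Tac1 was the 1 gene called over the list alone. Their adjusted p was 0.025, and adjusted p = 0.74 with an estimated correlation. The sensory neuron list rose by a median of 0.22 over 7 genes, led by the sodium channel Scn9a at 611.3 and 438.0 against 147.9 and 256.1 and Prph at 6654 and 5175 against 4560 and 3700, with an adjusted p of 0.0424, and adjusted p = 0.597 with an estimated correlation. The neutrophil and monocyte list fell by 1.10 over 6 genes, and the ependymal and cilium list fell by 0.21 over 9 genes, of which 6 were lower and 3 higher. These 2 lists had adjusted p of 1.7e-05 and 0.0257, and adjusted p = 0.597 for both with an estimated correlation. Of the 6 neutrophil and monocyte genes, 5 had an N-inv mean below the filter cutoff and passed it through the other arrays. The neutrophil granule gene Ngp measured 831.9 in PBS replicate 1 and 168.9 in PBS replicate 2, against 132.8 and 148.7 in N-inv, and Ltf measured 383.0 and 275.3 against 185.7 and 99.7. Ak7, an adenylate kinase of cilia, measured 232.5 and 329.5 in N-inv against 453.2 and 516.5, and Ccdc153 133.7 and 162.5 against 217.2 and 224.1. Without PBS replicate 1 the neutrophil and monocyte, pain neuropeptide and receptor and sensory neuron lists were no longer called, at -0.16, 0.05 and 0.09. The pain neuropeptide and receptor list also lost its call without N-inv replicate 2 (0.07), the sensory neuron list without either N-inv replicate (0.32 and 0.24), and the ependymal and cilium list without PBS replicate 2 (-0.03), N-inv replicate 2 (-0.01) or either SC replicate (-0.21). With no filter the pain neuropeptide and receptor, sensory neuron and ependymal and cilium lists were not called, at 0.07, 0.14 and -0.07, nor was the sensory neuron list with the replicate block (0.22). The neutrophil and monocyte list was at -1.97 without PBS replicate 2 and at -0.35 with no filter, the pain neuropeptide and receptor list at 0.20 without PBS replicate 2, and the ependymal and cilium list at -0.38 without PBS replicate 1 and -0.07 without N-inv replicate 1. The ependymal and cilium list kept its call in 5 of 14 alternatives, and lost it also with quantile normalization (-0.22), values as deposited (-0.24) and only the groups compared (-0.21).

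**Figure D2:**
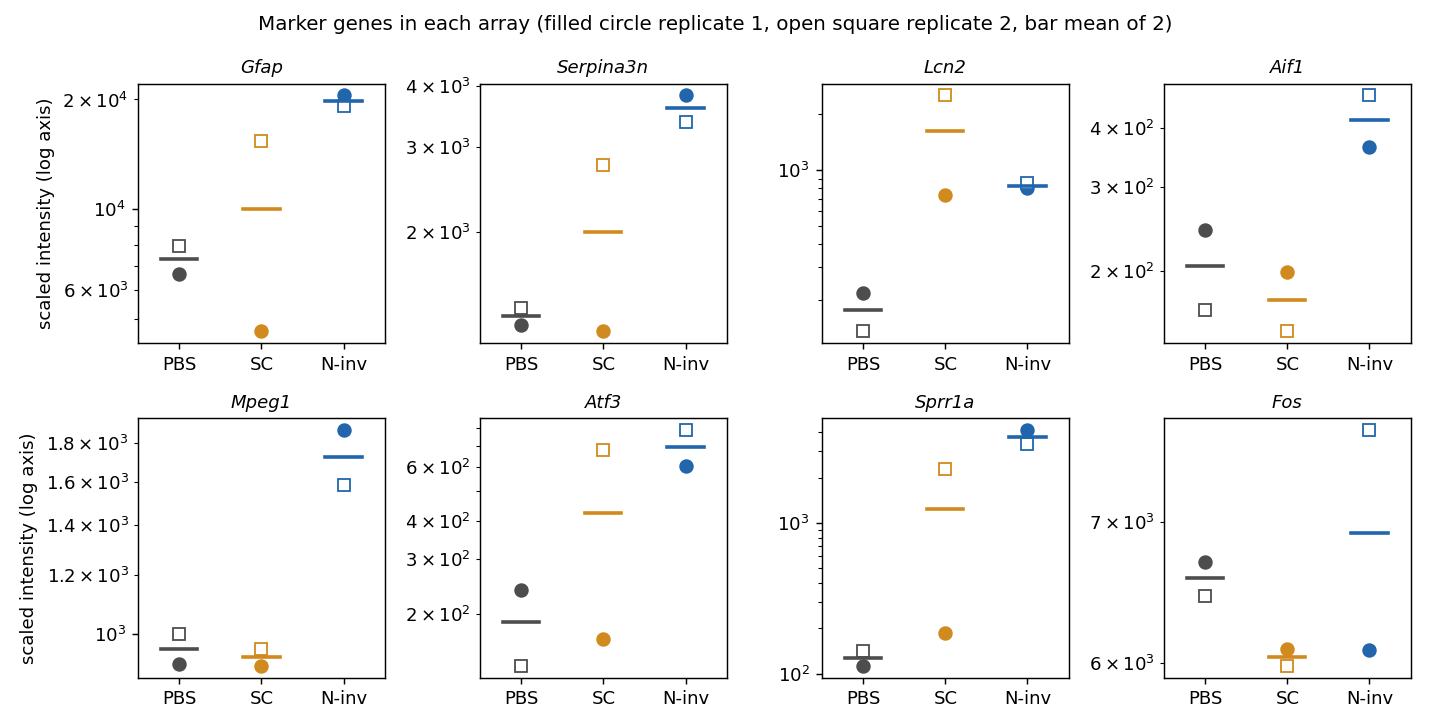
Scaled intensity (log axis) of 8 genes in each array, with the groups on the horizontal axis, replicate 1 as a filled circle, replicate 2 as an open square and the mean of both as a bar. Gfap and Mpeg1 in both N-inv arrays lie above all 4 control arrays, while the SC arrays lie apart for Gfap (4640 and 15370), Atf3 (166.1 and 681.0) and Sprr1a (187.1 and 2303).

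By the gap between arrays, the genes higher in N-inv than in PBS also included Cyp1b1, a cytochrome P450 (1600 and 1546 against 470.1 and 533.9), Ctla2a (3663 and 3098 against 1105 and 812.1) and the secreted neuronal protein Vgf (6330 and 6394 against 2749 and 2880). On the lower side stood Hspa1b, an inducible heat shock protein (634.6 and 1640 against 3988 and 7698), the potassium channel Kcnj13 (107.5 and 90.0 against 303.9 and 269.4), Ces5a (264.3 and 206.3 against 763.0 and 550.0) and Cdk5r2 (271.9 and 273.1 against 553.5 and 830.5). Pla2g2c measured 145.1 and 138.3 against 270.0 and 339.9, and the uncharacterised genes B230217O12Rik, 2700046A07Rik and 6720483E21Rik also lay lower. Fos, a marker of neuronal activity, measured 6913 ± 1172 in N-inv, 6581 ± 174 in PBS and 6036 ± 79.9 in SC (SD, n = 2 each). In limma 0 of 27022 probe sets passed the adjusted threshold, and 1097 had an unadjusted p under 0.05, 615 of them higher, where chance gives 1351. The smallest adjusted p was 0.283, for a second probe set of Depp1, at 40.6 and 66.9 in N-inv against 651.9 and 566.3 in PBS. With only the groups compared, Sprr1a alone passed, with an adjusted p of 0.0415.

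The second comparison set the nerve tumour model against the same cells under the skin, so that mice of both groups received tumour cells. Microglia genes rose in N-inv by a median log2 difference of 0.66 over 25 genes, of which 24 were higher and 13 were called over the list alone (adjusted p = 3.42e-11, and adjusted p = 0.161 with an estimated correlation). Ly86 measured 2132 and 1653 in N-inv against 810.5 and 805.8 in SC, the purinergic receptor P2ry12 941.5 and 1042 against 508.6 and 358.1, Mpeg1 1874 and 1582 against 907.6 and 956.5, and Laptm5 4404 and 3353 against 1940 and 1851. Genes of the glucocorticoid response fell by 0.71, with adjusted p = 1.71e-07, and adjusted p = 0.807 with an estimated correlation. Neutrophil and monocyte genes fell by 1.96, with adjusted p = 2.05e-05, and adjusted p = 0.582 with an estimated correlation. In fry the microglia list had an adjusted p of 0.0239 and was the 1 list called, while the other 7 lists called by camera were not. For change in either direction fry called 2 lists, microglia and oxidative phosphorylation, both with an adjusted p of 0.0102.

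All 25 glucocorticoid response genes were lower in N-inv than in SC, and 0 were called over the list alone. In N-inv against PBS this list had a median of -0.08 and an adjusted p of 0.0879 in camera. The sulfotransferase Sult1a1 measured 903.2 and 976.7 in N-inv and 1305 and 3205 in SC. Fkbp5, an immunophilin induced by glucocorticoids, measured 1315 and 1321 in N-inv, 1211 and 1241 in PBS, 1479 in SC replicate 1 and 5147 in SC replicate 2. The kinase Sgk1 measured 17680 and 5969 in N-inv and 14720 and 43880 in SC. Without SC replicate 2, the array with Xist, the median was 0.10 and the list was not called, and it was -1.32 without SC replicate 1 and -0.46 without N-inv replicate 2. The neutrophil genes S100a8, S100a9, Ngp and Camp measured 653.3 and 1581, 352.5 and 522.9, 526.5 and 1256, and 373.5 and 290.1 in SC. In N-inv they measured 109.6 and 162.2, 62.9 and 84.5, 132.8 and 148.7, and 72.1 and 95.1. Ltf measured 301.8 and 375.4 in SC and 185.7 and 99.7 in N-inv. In N-inv 5 of the 6 genes of this list had a mean below the filter cutoff, so they passed it through the other arrays. The size of the fall therefore depends in part on the filter. Of the 6 genes 5 were called lower over the list alone, and without SC replicate 1 the neutrophil and monocyte list, at -2.01, was no longer called, while with no filter it was at -1.29.

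Cholesterol synthesis genes lay 0.24 higher in N-inv than in SC over 20 genes, all of them higher, with Cyp51, a sterol demethylase, at 3767 and 4200 in N-inv against 2441 and 2612 in SC and Mvk, mevalonate kinase, at 1047 and 1053 against 807.8 and 745.4. Myelin genes lay 0.34 higher over 21 genes, including Mag, a glycoprotein of the myelin sheath, at 11220 and 9264 against 7001 and 5317 and Aspa at 6325 and 5928 against 4194 and 3315. In N-inv against PBS the medians of these 2 lists were -0.01 and -0.02, with adjusted p of 0.742 and 0.537 in camera. In SC against PBS they were -0.24 and -0.41, so N-inv lay above SC but not above PBS. Interferon genes rose by 0.40, MHC class II genes by 0.60 and MHC class I genes by 0.40, with Gbp6 at 700.7 and 495.3 against 208.0 and 333.9, Igtp at 1165 and 880.3 against 626.0 and 450.7, H2-Aa at 1388 and 1027 against 647.8 and 308.1, H2-DMa at 834.5 and 949.7 against 648.8 and 558.6, Psmb8 at 446.3 and 330.3 against 275.6 and 189.6 and B2m at 11400 and 9723 against 6890 and 8350. Over the list alone 1 of the 8 MHC class II genes was called and 0 in the other lists of this group. The adjusted p values of these 5 lists were 0.000487, 0.00201, 0.00303, 0.0339 and 0.0426. With an estimated correlation the adjusted p was 0.582 for cholesterol synthesis, myelin and MHC class II and 0.626 for interferon and MHC class I. Without SC replicate 2 the oligodendrocyte and myelin, interferon, MHC class II and MHC class I lists were no longer called, at 0.25, 0.21, 0.48 and 0.23, nor were the last 3 without N-inv replicate 1, at 0.18, 0.44 and 0.20. With a filter at the 60th percentile the interferon and MHC class I lists were not called, at 0.24 and 0.37, and cholesterol synthesis was at 0.15 without SC replicate 1. Beside these lists, the Actb 3' to 5' ratios were 3.81 and 4.71 in the SC arrays and 3.32 and 3.42 in the N-inv arrays, and those of Gapdh 3.52 and 3.38 against 3.13 and 3.38. Gfap measured 4640 and 15370 in SC by its brightest probe set. The log2 difference of that probe set between N-inv and SC was 1.23 ± 0.50 (SE), with an adjusted p of 0.546 in limma. The other tested probe sets of Gfap measured 4085 and 8900, and 3054 and 7070, in SC. Their log2 differences were 1.67 ± 0.34 and 1.82 ± 0.37 (SE), each with an adjusted p of 0.445 in limma. The reactive astrocyte and axon injury lists had medians of 0.17 and 0.17 and adjusted p of 0.162 and 0.206. Without SC replicate 1 these medians were 0.08 and -0.04, and without SC replicate 2 they were 0.31 and 0.40, the axon injury list then being called with an adjusted p of 0.0118.

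**Figure D3:**
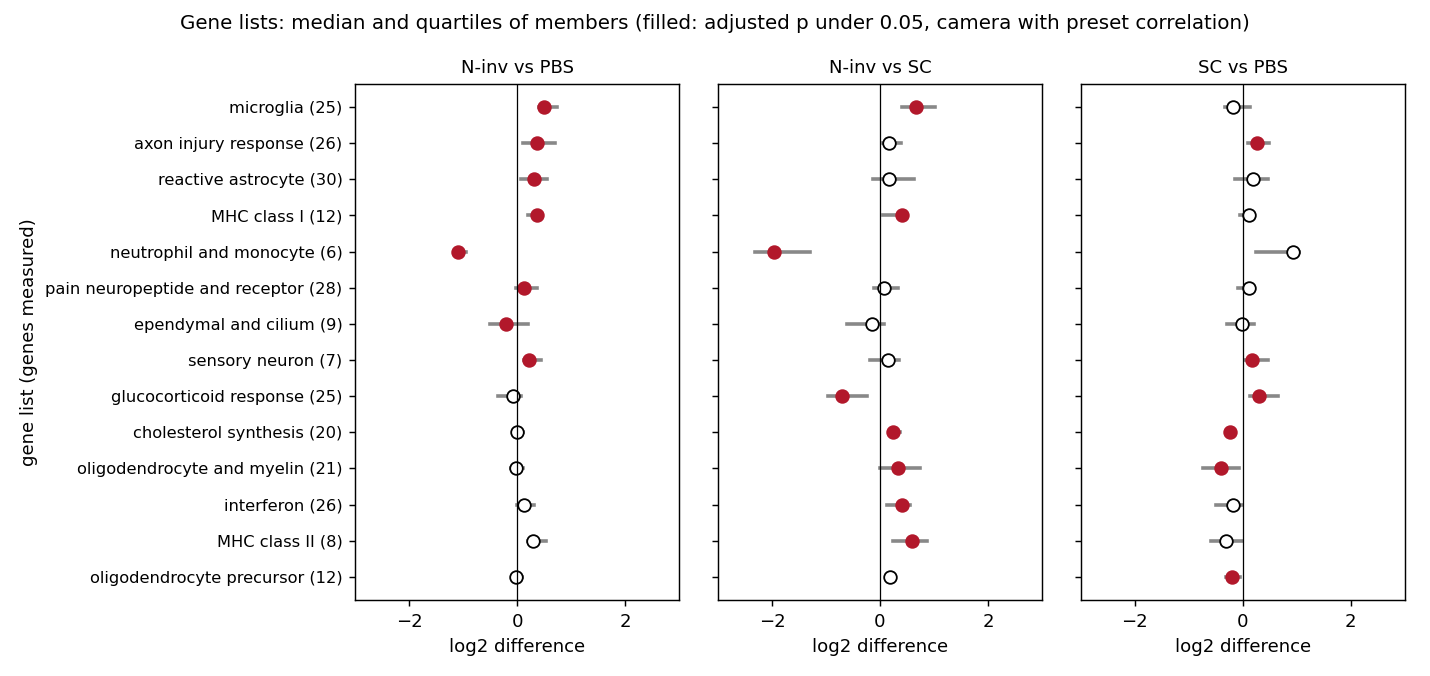
Median log2 difference (points) and quartiles (lines) of the members of the gene lists called in any of 3 comparisons, with lists on the vertical axis and filled points for an adjusted p under 0.05 in camera with the preset correlation. The microglia list lies at 0.50 and 0.66 in the comparisons of N-inv and at -0.18 in SC against PBS.

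Genes with the widest gap above SC were Scrn2 (359.8 and 321.6 against 36.2 and 77.7), the calcium sensor Kcnip3 (875.6 and 809.4 against 258.1 and 248.3), the protease inhibitor Serpinb1a (5535 and 4735 against 1579 and 1592), the imprinted gene Nnat (2983 and 2875 against 1271 and 1172), Tmem138, Nell2 and Ankrd23. Those below included Kcnj13 (107.5 and 90.0 against 343.0 and 329.0), Angpt2 (186.5 and 208.9 against 512.4 and 668.8), Depp1 (490.0 and 585.2 against 1457 and 1262) and Klrg2 (98.8 and 187.9 against 391.6 and 424.5). In limma 0 probe sets passed the adjusted threshold and 2417 had an unadjusted p under 0.05, 1610 of them higher in N-inv.

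The third comparison set tumour cells under the skin against vehicle. Myelin genes fell in SC by 0.41 over 21 genes, 18 of them lower, and cholesterol synthesis genes fell by 0.24 over 20 genes, 19 of them lower. Oligodendrocyte precursor genes fell by 0.19, with all 12 lower. Glucocorticoid response, axon injury and sensory neuron genes rose by 0.30, 0.26 and 0.17. These 6 lists, in the order given, had adjusted p of 0.000171, 0.000171, 0.0252, 0.000454, 0.000646 and 0.0465, and with an estimated correlation the adjusted p was 0.87 or 0.872 for each. In fry 0 lists were called, with a smallest adjusted p of 0.251. For change in either direction it called 4 lists, cholesterol synthesis, ribosomal protein, inhibitory neuron and preganglionic and autonomic, each with an adjusted p of 0.0255. The microglia list had a median of -0.18 and an adjusted p of 0.572, and without PBS replicate 1, PBS replicate 2 or SC replicate 2 the median was -0.10, 0.03 or -0.01.

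The kallikrein Klk6 measured 2441 and 1665 in SC against 4735 and 4222 in PBS, Aspa 4194 and 3315 against 6219 and 6182, and Ermn 11690 and 10030 against 16520 and 18080, while Apod lay higher, at 43050 and 52390 against 28170 and 33080. Cyp51 measured 2441 and 2612 against 4117 and 4401 and Dhcr7 1951 and 1924 against 2801 and 2746. Gpr17, a receptor of maturing oligodendrocyte precursors, measured 360.3 and 162.2 against 694.9 and 940.8, and the transcription factor Sox8 413.5 and 303.4 against 609.4 and 619.5. Among the lists that rose, Sult1a1 measured 1305 and 3205 against 1011 and 1067, Anxa1 897.1 and 1330 against 590.3 and 554.6, and Pou4f1 and Isl1, transcription factors of sensory neurons, 818.1 and 892.7 against 564.7 and 553.1 and 545.9 and 532.6 against 386.5 and 452.9. Stmn4 of the axon injury list lay lower, at 6384 and 5285 against 8983 and 8273. Over the list alone 3 myelin, 1 cholesterol synthesis, 2 precursor, 1 glucocorticoid response, 0 axon injury and 1 sensory neuron genes were called. The Actb 3' to 5' ratios were 3.81 and 4.71 in the SC arrays and 3.05 and 3.57 in the PBS arrays, and those of Gapdh 3.52 and 3.38 against 2.82 and 3.02. Without SC replicate 2, cholesterol synthesis, at -0.32, was the single list of these 6 still called, and the glucocorticoid response, axon injury response, oligodendrocyte and myelin, oligodendrocyte precursor and sensory neuron lists had medians of -0.28, -0.01, -0.28, -0.32 and 0.34. The oligodendrocyte precursor list was also lost without SC replicate 1 (-0.11) or PBS replicate 2 (-0.16), and the sensory neuron list without SC replicate 1 (0.33) or PBS replicate 1 (0.14), and was at 0.45 without PBS replicate 2. Without SC replicate 1 the glucocorticoid response and axon injury lists were at 0.94 and 0.53. The sensory neuron list kept its call in 4 of 14 alternatives, and lost it also with no filter (0.05), quantile normalization (0.19), values as deposited (0.19), an intensity trend (0.17), the replicate block (0.17) and the mean over probe sets (0.12).

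**Figure D4:**
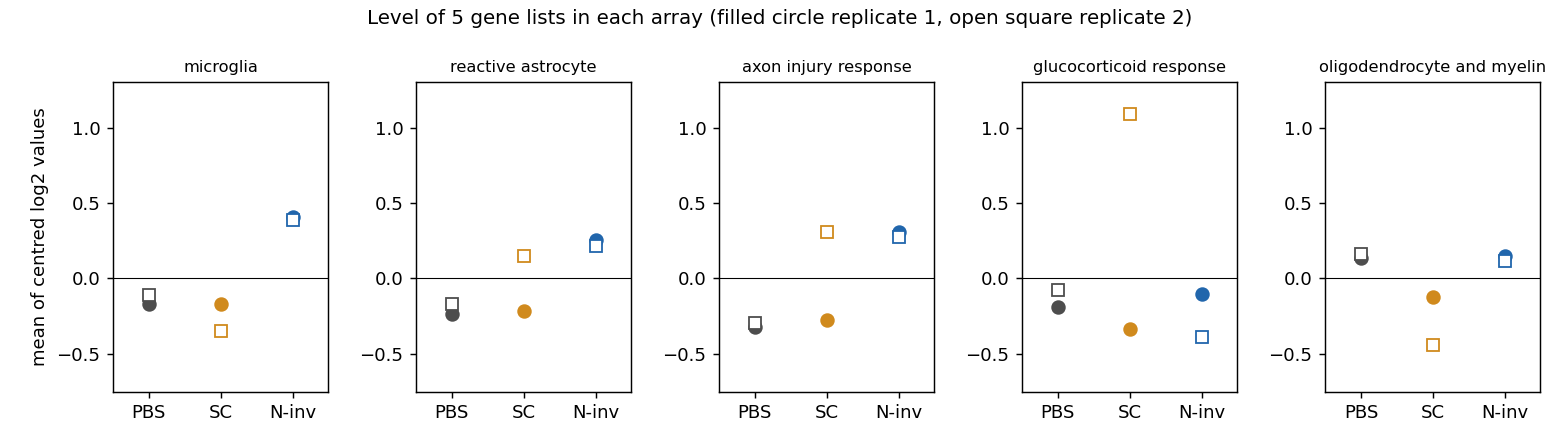
Mean over the genes of 5 lists of the log2 value centred on each gene's mean over the 6 arrays, with groups on the horizontal axis and replicates as filled circles and open squares. SC replicate 2 stood at 1.09 for the glucocorticoid list and at 0.31 for the axon injury list, against -0.34 and -0.28 in SC replicate 1.

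Lcn2, which both lists of glucocorticoid and reactive astrocyte genes hold, measured 736.2 and 2530 in SC against 217.7 and 135.3 in PBS. The genes with the widest gap above PBS also included Lrg1 (389.2 and 405.2 against 125.2 and 174.1), Gpx3, a secreted glutathione peroxidase (1711 and 1392 against 453.5 and 657.1), the stress neuropeptide Crh (1132 and 779.7 against 339.1 and 402.3), Tlr9, Capn8, Afmid and Rpp21. Those below were Serpinb1a (1579 and 1592 against 4341 and 3901), the myelin protein Pmp2 (375.7 and 35.5 against 931.5 and 1336), Pdlim2 (1273 and 1235 against 3098 and 2881), Prr18 (2350 and 2367 against 5108 and 5321), Lekr1, Kcnip3, E330020D12Rik and Scrn2. Gfap measured 10010 ± 7590 in SC (SD, n = 2), and 2 of its 3 probe sets had a log2 difference from PBS of the opposite sign to the brightest, which was at 0.22 ± 0.50 (SE). In limma 0 probe sets passed the adjusted threshold and 2141 had an unadjusted p under 0.05, 1396 of them lower in SC. Without SC replicate 1, 9 probe sets passed, including those of Xist and Sprr1a.

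The last comparison set N-inv against the mean of both controls. Microglia genes rose by a median of 0.61 over 25 genes, 24 of them higher and 15 called over the list alone, with Mpeg1 at 1874 and 1582 against 907.6 to 1001 in the 4 control arrays. The microglia list had an adjusted p of 9e-18, and adjusted p = 0.0822 with an estimated correlation. In fry its adjusted p was 0.0258, and 0.00491 for change in either direction, and it was the 1 list called by each. Axon injury, MHC class I and reactive astrocyte genes rose by 0.30, 0.40 and 0.22, and interferon, MHC class II, astrocyte and cholesterol synthesis genes by 0.28, 0.41, 0.16 and 0.12. Neutrophil and monocyte genes fell by 1.49, glucocorticoid response genes by 0.43 and ependymal genes by 0.10. The adjusted p of these 10 lists lay between 9.26e-07 and 0.0318, and with an estimated correlation the adjusted p lay between 0.613 and 0.776. Against PBS alone the cholesterol synthesis, glucocorticoid response and interferon lists were at -0.01, -0.08 and 0.12 and were not called. Nor were the MHC class II and astrocyte lists against PBS alone, at 0.30 and 0.10. Against SC alone the axon injury, reactive astrocyte, astrocyte and ependymal lists were not called, at 0.17, 0.17, 0.15 and -0.14. Without SC replicate 2 the glucocorticoid response, interferon, MHC class II, ependymal and cilium and cholesterol synthesis lists were not called, at -0.03, 0.20, 0.37, -0.12 and 0.19. Without N-inv replicate 1 the MHC class I, MHC class II, interferon, astrocyte and cholesterol synthesis lists were not called, at 0.24, 0.15, 0.15, 0.18 and 0.13, and the ependymal and cilium list was not called without N-inv replicate 2 (-0.01), nor MHC class II without PBS replicate 1 (0.38). The astrocyte list was also lost without N-inv replicate 2 (0.17), PBS replicate 1 (0.16) or SC replicate 1 (0.10), and the cholesterol synthesis list was lost with any of the 6 arrays left out, at 0.07 to 0.19. Without SC replicate 1 the axon injury list was at 0.19, the glucocorticoid response list at -0.74 and the ependymal and cilium list at -0.25. Without SC replicate 2 the MHC class I list was at 0.24, and without N-inv replicate 2 the glucocorticoid response list was at -0.22. The ependymal and cilium list was at -0.22, -0.05 and -0.20 without PBS replicate 1, PBS replicate 2 and N-inv replicate 1. With no filter the reactive astrocyte list was at 0.35 and the neutrophil and monocyte list at -0.91. Calls were also lost with quantile normalization for cholesterol synthesis (0.06) and for the ependymal and cilium list (-0.09), with no filter for the latter (-0.06), and with the mean over probe sets for the astrocyte list (0.11).

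Over the list alone 5 neutrophil and monocyte genes and 1 ependymal gene were called lower, and 0 genes in the other 8 of these lists. In N-inv, 5 neutrophil and monocyte genes had a mean below the filter cutoff and passed it through the control arrays. Of the astrocyte list, Ntsr2 measured 13020 and 12000 in N-inv against 7490 to 10410 in the controls, and Mlc1 8126 and 7962 against 4888 to 7110.

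Nnat measured 2983 and 2875 in N-inv and between 1172 and 1591 in the controls, Ankrd23 301.7 and 320.4 against 116.8 to 147.9, and the urea transporter Slc14a1 1730 and 1538 against 754.2 to 966.1. Plscr2, Sft2d3, Naprt and the interleukin 13 receptor subunit Il13ra1 also had both N-inv arrays above all 4 controls. Kcnj13 measured 107.5 and 90.0 against 269.4 to 343.0, Depp1 490.0 and 585.2 against 901.1 to 1457, and Ces5a 264.3 and 206.3 against 462.1 to 763.0. Iqcc, Sec14l3, Cldn19 and B230217O12Rik also lay below all 4 controls, as did the brighter of the 2 probe sets of 2700046A07Rik, while its other probe set had a difference of the opposite sign. The groups did not overlap for 13.7% of probe sets, where chance gives 13.3%. In limma 0 probe sets passed the adjusted threshold and 1560 had an unadjusted p under 0.05, 936 of them higher. The smallest adjusted p was 0.112, for a probe set of Depp1.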

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

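The tests on leukocytes, neuron share, Y-linked genes and ganglion or root tissue were chosen after the results they bear on had been seen, while those on vessel and meninges macrophages and on genes escaping X inactivation were written before.

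Xist gave a signal in SC replicate 2 in a probe set that the comparisons do not use, 10250 against 60.9 at most in PBS. RNA of a female mouse alone, or mixed in at an equal share, would lower the Y-linked genes Eif2s3y, Kdm5d and Uty, but their median log2 difference from the other 5 arrays was 0.21. A second X chromosome in a male animal would raise genes that escape X inactivation. Those genes, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, lay 0.49 to 0.74 higher, with a median of 0.65, against -0.23 to -0.10 for the same measure in each other array and at the 99.9th percentile of 10000 random sets of 4 genes matched on mean expression. An extra X chromosome may therefore account for the signal, as a hypothesis from 1 array, while a smaller share of female RNA was not tested and the design offers no biological explanation.

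The microglia list was higher in both N-inv arrays than in PBS, with quartiles of 0.40 and 0.73. A lower share of neurons would raise other cell types alike, but the highest median among astrocyte, oligodendrocyte, precursor, endothelial and mural cell lists was 0.10, and the neuron list was at 0.11. More macrophages of the meninges and vessel walls are argued against by 7 of their genes, including Mrc1, Cd163 and Lyve1, with a median of -0.05 and 0.12 at most over the pairs. More blood leukocytes stay open: the neutrophil and monocyte list was at -1.10, and between -2.12 and -0.05 over the 4 pairs of arrays, but 5 of its 6 genes lay below the filter in N-inv and the median was -0.16 without PBS replicate 1. RNA quality, given the Gapdh ratios, and the nerve tumour itself also stay open and untested, and these arrays do not separate more microglia from more expression per cell.

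The axon injury list was higher in N-inv than in PBS, and in SC replicate 2. Ganglion tissue dissected along with the cord could bring Sprr1a and Atf3, and 7 genes restricted to sensory neurons, including Scn10a and Trpv1, had a median of -0.76, but all lay below the filter, at a median intensity of 80.0 against its 147.7, where they exclude nothing. The sensory neuron list above the filter went the other way, with a median of 0.22 and 6 of 7 genes higher, including Scn9a and Prph. That list shares 2 genes with the motor neuron list and 1 with the pain neuropeptide list, so its genes are not all particular to ganglia. Ganglion tissue stays open. Nerve root tissue could do so too, and the Schwann cell list had a median of -0.01, with -0.19 to 0.24 over the pairs of arrays, which leaves it open. An injury response of cord neurons also stays open.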

How the results depend on the processing

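The fit with only the groups compared was chosen for lists after the data were seen, and for the mean of both controls it equals the fit over all arrays and was not run. Counts of calls were 0 in each comparison. An unadjusted p under 0.01 with a fold of 2 and no overlap gave 60 for N-inv against PBS, 134 for N-inv against SC, 127 for SC against PBS and 50 for N-inv against both controls. An intensity trend gave 1, 2 and 1 for the comparisons of N-inv with PBS, SC and both controls, a pseudocount at the median gave 1 for SC and 1 for both controls, and only the groups compared gave 1 for PBS. Leaving out 1 array gave 0 to 1, 0 to 1, 0 to 9 and 0 to 1 calls in that order of comparisons, with 9 without SC replicate 1. A lone array is then assumed to vary like the other groups.

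The count of lists called fell to 0 in all 4 comparisons with an estimated correlation, and rose from 8 to 15 with an intensity trend for N-inv against PBS. Leaving out 1 array gave 7 to 9, 5 to 10, 2 to 7 and 6 to 11 lists, and the lowest in the last 3 came without SC replicate 2. The microglia list was called in 14 of 15 alternatives for N-inv against PBS, with medians of 0.47 to 0.65, and in 14 of 15 for N-inv against SC, with 0.60 to 0.72, the exception being the estimated correlation. The glucocorticoid list in SC against PBS reversed to -0.28 without SC replicate 2 and was 0.94 without SC replicate 1, and the cause was not tested. With no filter the sensory neuron list in N-inv against PBS kept a positive median, 0.14, while its direction relative to other genes in camera turned downward, and the cause was not tested.

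Named genes kept their direction and side of the threshold in 787 of 791 values for N-inv against PBS and 846 of 848 for N-inv against SC. They did so in 759 of 763 for SC against PBS and 1012 of 1014 for N-inv against both controls, and 6 reversed. Genes named by the gap between arrays cannot change direction when an array is left out, and no gene was called in the main fit. These counts therefore say little about stability. The 6 reversals were of Gfap, Atf3, Aif1 and Fos. Gfap in SC against PBS was -0.23 with the mean over its probe sets. Leaving out 1 array gave -0.64 to 1.08 for Gfap, -0.11 to 1.77 for Atf3 and -0.44 to 0.05 for Aif1 in SC against PBS, with the lowest of Gfap and Atf3 without SC replicate 2. Fos was -0.11 to 0.23 in N-inv against PBS and -0.05 to 0.30 against both controls, lowest without N-inv replicate 2. The cause was not tested. The correlations of deviations of same-numbered arrays were 0.041, 0.01 and -0.032. They show no strong effect shared by same-numbered arrays over these genes. With 1 deviation per group, they cannot tell whether samples were handled in pairs. The replicate block gave 0 calls in each comparison and 7, 8, 6 and 11 lists. Dim probe sets limit what can be seen, since those below an intensity of 147.7 were not tested.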

Other observations

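The values of Crh and Hspa1b across all groups were set side by side after they had been seen, and no test was chosen for them. Other gene lists gave these values. In N-inv against PBS the neuron list had a median of 0.11 over 22 genes, the motor neuron list 0.12 over 15, the complement list 0.17 over 12 and the MHC class II list 0.30 over 8, with adjusted p of 0.0593, 0.556, 0.0593 and 0.184 in camera. The MHC class II list was at 0.07 without N-inv replicate 1 and at 0.59 without N-inv replicate 2, where it was called with an adjusted p of 0.00123. The complement list was at 0.11 without PBS replicate 2 and 0.26 without N-inv replicate 2, the neuron list at 0.05 without PBS replicate 1 and the motor neuron list at 0.06 without N-inv replicate 1. The complement list was called with no filter (0.18), a filter at the 60th percentile (0.27), quantile normalization (0.17), values as deposited (0.14), an intensity trend (0.17), the mean over probe sets (0.17) and without PBS replicate 1 (0.21), and the MHC class II list with that filter (0.37) and that trend (0.30). The neuron list was called with that filter (0.11), values as deposited (0.08), that trend (0.11), only the groups compared (0.11) and without either SC replicate (0.11). The immediate early list was at -0.08 over 26 genes, and the lists of fasting and lipid oxidation and of oxidative phosphorylation were at 0.03 and 0.03, and at -0.15 to 0.04, -0.01 to 0.10 and 0.02 to 0.06 with single arrays left out. In SC against PBS the neutrophil and monocyte list was at 0.93 over 6 genes, with an adjusted p of 0.164, and the value rests on PBS replicate 2. Without that array it was -0.02, and without PBS replicate 1 it was 1.87, with an adjusted p of 6.49e-07. It was 0.61 without SC replicate 2, and with no filter 0.82 with an adjusted p of 0.0233. The interferon list was at -0.17 over 26 genes, with an adjusted p of 0.0621, and at -0.07 without SC replicate 2. It was called without SC replicate 1 (-0.19) or either N-inv replicate (-0.17), with only the groups compared (-0.17) and with the replicate block (-0.17).

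The stress neuropeptide Crh measured 979.2 and 865.3 in N-inv and 1132 and 779.7 in SC, against 339.1 and 402.3 in PBS. All 4 arrays of mice that received tumour cells thus lay above both PBS arrays. Crh was not called, with an adjusted p in limma against PBS of 0.94 for N-inv and 0.492 for SC. Hspa1b measured 3988 and 7698 in PBS against 634.6 and 1640 in N-inv and 2767 and 1215 in SC.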
